A study of Mus musculus with 12 samples.

How the data were processed

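RNA was sequenced from OT-I CD8 T cells taken before activation (Naive) and 24, 48 and 72 h after its start, with 3 libraries in each of the 4 groups. The authors deposited TPM, reads scaled by transcript length and library total, in 12 libraries, and each library summed to 1000000. The submitters' processing notes name FastQC 0.11.9, STAR 2.7.7a, cutadapt 2.9 and edgeR 3.36.0 and the GRCm39 build. The tool that counted reads, the strand setting and the treatment of reads shared between genes are not given in the sources used here. The number of animals behind each replicate is not given either. Reads were recovered from the TPM values as whole numbers, within a tolerance of 0.001, and came to between 14312854 and 19495722 per library. They may be low by a whole factor for some genes, and were used for depth and for 1 alternative fit.

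TPM values were taken as log2(TPM + 1). Genes with at least 1 TPM in at least 3 of the 12 libraries were tested (12630 genes, of 19181 with a value above 0 in any library). A linear model with 4 group means was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend. The 5 comparisons were each later time against Naive, 48h vs 24h and 72h vs 48h, and p-values were adjusted by Benjamini-Hochberg over the genes tested in each. A gene was called higher or lower at an adjusted p under 0.05 with an absolute log2 fold change of at least 1, and Klhl6 and Foxo1, which the series title names, were judged by adjusted p alone. All tests were 2-sided. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

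The tests, the alternatives and 30 gene lists were fixed before the data were examined, unless stated otherwise. Lists with at least 5 members tested were tested with limma camera at a preset correlation of 0.01, adjusted over 140 tests, then with an estimated correlation and with fry, which asks whether the genes of a list move on balance in 1 direction and compares them with no other genes. Genes were named by a rule fixed at the same time. It took Klhl6 and Foxo1, and in each comparison the 8 genes of largest rise and the 8 of largest fall among those called, with a mean of at least 10 TPM in the higher group and no overlap between libraries. It also took up to 4 called members of each list with at least 5 TPM, and 14 genes of checkpoint, memory, effector and growth biology. List members that were not called, such as Foxo3 at 24h, were named with their values. Some genes the rule named are not reported here, and they still count in the totals of lists and of named genes.

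Alternatives changed 1 choice at a time: a pseudocount of 0.1 or 5, no filter or a filter of 5 TPM, median-of-ratios scaling, quantile normalization, a replicate block, no intensity trend, a fit on the compared groups only, library weights, no fold minimum, limma treat, and each library left out. A limma voom fit on recovered reads and a fit without the 3 Naive libraries were chosen after seeing the data. The test was tried on simulated data with 200 changed genes, where it called 100% of genes simulated at a 4-fold change and 18% of those at a 2-fold change, which lies at the fold minimum. By adjusted p alone, as Klhl6 and Foxo1 were judged, 98% of the genes at a 2-fold and 98% at a 1.5-fold change passed. In the same data 1 of 12209 unchanged genes was called. The simulation gave every gene the same spread between replicates, a dispersion of 0.00232, the median over well-covered genes. Klhl6 at 24h and Foxo1 in Naive varied more than that, so these shares do not describe them or other genes of larger spread. Genomic positions are not given, because the annotation at hand is for another build.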

Results

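RNA was sequenced from CD8 T cells of OT-I mice, whose T cells carry a transgenic receptor for an ovalbumin peptide. Unstimulated cells from the spleen formed the Naive group. The submitters' extraction notes speak of transferred OT-I T cells, and whether this applies to these libraries is not given. The other groups were collected 24, 48 and 72 h after the start of activation with antibodies to CD3 and CD28 in the presence of IL-2. The antibodies stimulate the T cell receptor (TCR) complex and a costimulatory receptor. Activation lasted 48 h, and the cells were then moved off the activation plates, so the 72h cells had spent their last day without the plates. Each group held 3 libraries, described by the submitters as biological replicates, which gave 12 libraries in all. Expression was deposited as TPM, a unit that scales reads by transcript length and library total. Whole reads recovered from these values came to between 14312854 and 19495722 per library. The first principal component held 75.8% of the variance and separated the Naive libraries from all others, and the second held 12.6% and ordered the 3 activated groups. Across the 4 groups, 11889 of 12630 genes tested differed (94.1%, limma F test).

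The title of the series places Klhl6 and Foxo1 at its centre, and the time course shows how both transcripts behaved through activation. Klhl6 (ENSMUSG00000043008), which encodes a BTB-kelch adaptor of a cullin-3 ubiquitin ligase, stood at 179 ± 17.2 TPM in Naive cells (mean ± SD, n = 3 here and below). It was at 43.2 ± 7.14 TPM at 24h, 35.2 ± 2.10 at 48h and 74.8 ± 4.08 at 72h. Against Naive its log2 fold change was −2.03 at 24h, −2.31 at 48h and −1.24 at 72h (SE 0.10 in each, limma adjusted p = 6.75e-10, 2.07e-10 and 1.18e-07). This fit pooled 1 spread over the 4 groups, although the Naive replicates were less alike (Pearson r 0.984 to 0.99 on log2(TPM + 1)) than those of the other groups (0.995 to 0.996). A limma fit on the 2 groups alone gave Klhl6 an adjusted p of 2.51e-06 at 24h vs Naive. Klhl6 rose again by 1.07 between 48h and 72h (adjusted p = 5.62e-06), with all 72h libraries above all 48h libraries and below all Naive libraries. Foxo1 (ENSMUSG00000044167), which encodes a forkhead transcription factor of quiescent T cells, fell from 125 ± 18.0 TPM in Naive to 47.1 ± 1.26 at 24h, and was at 53 ± 1.98 at 48h and 60.5 ± 3.73 at 72h. Its log2 fold changes against Naive were −1.38, −1.21 and −1.03 at the 3 times (SE 0.09, adjusted p = 9.04e-09, 3.59e-08 and 2.10e-07). Between 48h and 72h Foxo1 differed by 0.18 (adjusted p = 0.125), which did not pass the threshold. It passed with a fit on the 2 groups (adjusted p = 0.0356), with library weights (0.19, adjusted p = 0.00916) and, chosen after seeing the data, without the 3 Naive libraries (adjusted p = 0.0172).

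**Figure D1:**
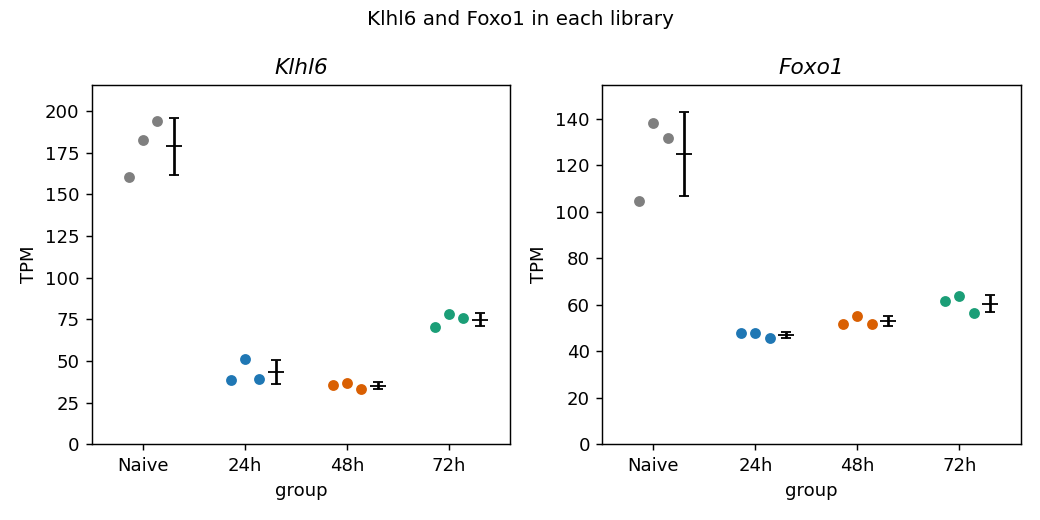
TPM of Klhl6 (left) and Foxo1 (right) in each of the 12 libraries by group. Points are libraries, and the bar beside them gives the mean and SD of the 3. Klhl6 stood at 179 TPM in Naive, 35.2 at 48h and 74.8 at 72h, and Foxo1 at 125, 53 and 60.5.

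The step from 24h to 48h was small for both genes. Klhl6 differed by −0.28 (adjusted p = 0.0405), a call lost without 24h replicate 2 (−0.15) or 48h replicates 1 (−0.29), 2 (−0.31) or 3 (−0.23), and with median-of-ratios scaling (−0.24). Foxo1 differed by 0.17 (adjusted p = 0.144), and passed the threshold with median-of-ratios scaling (0.21, adjusted p = 0.0273). Among the related forkhead genes, Foxo4 went from 65.2 ± 11.5 TPM in Naive to 11.9 ± 0.623 at 24h and 15.9 ± 0.907 at 72h, a log2 fold change of −2.34 and −1.96. Foxo3 stood at 41.8 ± 5.54 TPM in Naive and 29.1 ± 1.15 at 24h, where its log2 fold change of −0.50 lay under the fold minimum, and it fell by 1.03 by 72h. Without Naive replicate 3 or 72h replicate 3 the Foxo3 change lay under the fold minimum (−0.95 and −0.97). Of 29 cullin-3 and BTB-kelch adaptor genes tested, 3 rose and 6 fell at 24h vs Naive, and the list did not pass (camera adjusted p = 0.77, and adjusted p = 0.913 with an estimated correlation). Klhl24 fell by 3.74 and Kbtbd2 by 1.92, beside Klhl6, while Kbtbd8 rose by 1.66. The list's median was 0.06 and its mean −0.09, and the median turned negative with median-of-ratios scaling and with quantile normalization.

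At 24h vs Naive, the comparison that shows the first day of activation, 3245 genes rose and 2657 fell. Il2ra, the high-affinity chain of the IL-2 receptor, went from 1.26 ± 0.28 to 447 ± 11.8 TPM. The cytotoxic protease Gzmb went from 58.1 ± 20.5 to 7120.0 ± 681 TPM, the cytokine Ifng from 21.7 ± 7.74 to 1250.3 ± 183, and the chemokine Xcl1 from 16.4 ± 14.2 to 1979.9 ± 62.0. Klf2, a transcription factor of quiescence, dropped from 4452 ± 349.6 to 6.52 ± 0.662 TPM, and S1pr1, the receptor that lets lymphocytes leave lymphoid tissue, from 1136 ± 135 to 4.09 ± 1.32. On the log2 scale these changes were 7.64 (SE 0.08) for Il2ra, 6.98 for Gzmb, 5.84 for Ifng, 7.14 for Xcl1, −9.21 (SE 0.08) for Klf2 and −7.83 for S1pr1. The 16 genes of largest change also held Tnfrsf9 (6.14), the costimulatory receptor 4-1BB, Nrn1 (6.25), Zbtb32 (5.86) and the cytokine Lif (5.82) on the higher side. On the lower side they held Fosb (−7.63), the globin genes Hba-a2 (−7.97) and Hbb-bs (−7.52), the complement genes C1qa (−7.62) and C1qb (−7.30), and Fcna, which was listed at 0 in all 24h libraries and at 170.4 TPM in Naive.

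Genes of the resting state were counted at 24h vs Naive. Of 25 naive and quiescence genes, 18 fell and 2 rose (camera adjusted p = 5.98e-07, and adjusted p = 0.203 with an estimated correlation). Il7r, the IL-7 receptor, stood at 216 ± 35.4 TPM in Naive and 19.1 ± 1.76 at 24h, and Tcf7, a transcription factor of naive and stem-like T cells, at 1211 ± 173 and 219 ± 30.9. Klf3 fell by 4.05 and Nsg2 by 3.72. Of 25 FOXO target genes, 21 fell and none rose (camera adjusted p = 3.06e-09, and adjusted p = 0.203 with an estimated correlation), among them Klf4 (−5.12) and Pik3ip1 (−4.83), a negative regulator of PI3K, and this list shares members such as Klf2, S1pr1, Il7r and Tcf7 with the preceding one. Of 23 chemokine and homing receptors, 3 rose and 13 fell (camera adjusted p = 1.92e-04, and adjusted p = 0.203 with an estimated correlation). Ccr4 rose by 4.57, while Cxcr4 fell by 6.29 and Ccr9 by 4.32.

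Checkpoint and exhaustion-associated genes split at 24h. Of 17 inhibitory receptors, 5 rose and 6 fell (camera adjusted p = 0.546, and adjusted p = 0.743 with an estimated correlation), and fry placed this list on the higher side where camera placed it on the lower (adjusted p = 0.346). Pdcd1, which encodes PD-1, went from 1.52 ± 0.748 to 96.5 ± 5.31 TPM (log2 fold change 5.32), Lag3 from 18.3 ± 7.79 to 137 ± 9.90 (2.92), and Cd200 rose by 5.13, while Klrg1 fell by 4.09 and Entpd1 by 3.07. Tigit (0.64), Ctla4 (0.55) and Havcr2 (−0.99) lay under the fold minimum at 24h. Havcr2 was called lower with median-of-ratios scaling (−1.22) and without Naive replicate 3 (−1.18), 24h replicate 1 (−1.12) or 24h replicate 3 (−1.06). Of 20 exhaustion-associated regulators, 4 rose and 7 fell (camera adjusted p = 0.354, and adjusted p = 0.602 with an estimated correlation). Rbpj (3.11) and Irf4 (2.82), a transcription factor downstream of the TCR, rose, while Maf fell by 3.11 and Tox, a transcription factor of exhausted T cells, fell from 21.3 ± 2.69 to 8.41 ± 0.549 TPM (−1.24).

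Effector and TCR-induced genes also moved in both directions. Of 34 effector and cytotoxic genes, 12 rose and 10 fell (camera adjusted p = 0.914, and adjusted p = 0.974 with an estimated correlation), with a median of 0 and a mean of 0.77 where camera placed the list on the lower side, and fry (adjusted p = 0.000328) and camera with median-of-ratios scaling (0.769) on the higher side. The chemokine Ccl3 rose by 5.72. Of 30 TCR-induced early genes, 14 rose and 10 fell (camera adjusted p = 0.603, and adjusted p = 0.775 with an estimated correlation). Myc, a driver of growth in activated T cells, went from 96.9 ± 11.6 to 618 ± 32.4 TPM (2.67), whereas Fos fell by 5.55 and 10 members of this list were called lower than Naive at all 3 times. Of 25 IL-2 and STAT5 responsive genes, 16 rose and 2 fell (camera adjusted p = 0.0114, and adjusted p = 0.211 with an estimated correlation), Lta by 5.10.

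Genes of division and growth were counted next. All but 1 of 40 cell cycle genes rose (39 genes, camera adjusted p = 4.27e-11, and adjusted p = 0.211 with an estimated correlation), including Mcm10 (4.40), Cdc45 (4.24), Rrm2 (4.20), Ccnb1 (4.07) and Mki67, which went from 27.8 ± 0.74 to 209 ± 14.6 TPM (2.86). Of 30 ribosome biogenesis genes, 30 rose (camera adjusted p = 1.80e-09, and adjusted p = 0.203 with an estimated correlation), Nop2 by 3.15 and Nop16 by 3.14. None of 30 cytosolic ribosomal protein genes was called, with a median of −0.49, or −0.77 with median-of-ratios scaling and −0.29 with quantile normalization (camera adjusted p = 2.38e-04, and adjusted p = 0.303 with an estimated correlation). Of 21 glycolysis genes, 18 rose (camera adjusted p = 9.70e-05, and adjusted p = 0.465 with an estimated correlation), Tpi1 by 4.33 and Hk2 by 4.24. The glucose transporter Slc2a1 rose by 1.01, a call lost without Naive replicate 1 (0.94), 24h replicate 1 (0.87) or 24h replicate 3 (0.90), and with median-of-ratios scaling (0.73). Of 33 nuclear respiratory chain genes, 17 rose (camera adjusted p = 3.11e-05, and adjusted p = 0.303 with an estimated correlation), Cycs by 2.23 and Ndufab1 by 1.88. Of 13 mitochondrial genome genes, 7 fell (camera adjusted p = 0.00753, and adjusted p = 0.502 with an estimated correlation), mt-Atp6 by 1.45 and mt-Cytb by 1.28, both under the fold minimum with quantile normalization (−0.72 and −0.996). With it the list did not pass (camera adjusted p = 0.209), its median went from −1.06 to −0.46, and mt-Co1 (−1.43) and mt-Co3 (−1.21) lost their calls too (−0.46 and −0.07).

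Anabolic and stress genes were counted at 24h as well. Of 21 amino acid transport, serine and one-carbon genes, 17 rose and 1 fell (camera adjusted p = 5.66e-05, and adjusted p = 0.211 with an estimated correlation), led by Shmt1 (4.74), Asns (4.28), Psat1 (4.18) and Mthfd2 (3.87), enzymes of serine, asparagine and folate metabolism. Of 24 cholesterol synthesis genes, 19 rose (camera adjusted p = 2.51e-05, and adjusted p = 0.332 with an estimated correlation), Idi1 by 4.01 and Sqle by 3.23. Of 18 integrated stress response genes, 5 rose and 5 fell (camera adjusted p = 0.797, and adjusted p = 0.919 with an estimated correlation), and Ppp1r15a fell by 3.53. Of 20 unfolded protein response and folding genes, 10 rose and 3 fell (camera adjusted p = 0.135, and adjusted p = 0.587 with an estimated correlation), with Sdf2l1 at 2.10 and Dnajb9 at −3.50 on the log2 scale. Of 30 interferon-stimulated genes, 4 rose and 15 fell (camera adjusted p = 0.0199, and adjusted p = 0.445 with an estimated correlation). Gbp2 (4.49) and Igtp (3.19), both guanylate-binding or related GTPases, rose while Oas2 fell by 3.59 and Irf7 by 3.56. Of 24 apoptosis and p53 response genes, 8 rose and 4 fell (camera adjusted p = 0.708, and adjusted p = 0.775 with an estimated correlation), with Bcl2l1, an inhibitor of apoptosis, at 4.06 and Bbc3, a promoter of apoptosis, at −5.07. Of 16 replication-dependent histone genes, 9 rose and 2 fell (camera adjusted p = 0.312, and adjusted p = 0.472 with an estimated correlation), with Hist1h3c at 4.90 and Hist1h1c at −6.79.

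Markers of other cell types were present in the Naive libraries. Of 20 myeloid markers, 20 fell at 24h (camera adjusted p = 3.36e-08, and adjusted p = 0.29 with an estimated correlation), and C1qa was at 262 ± 112 TPM in Naive and 0.254 ± 0.235 at 24h. Lyz2, an abundant myeloid transcript, was at 739, 336 and 218 TPM in Naive replicates 1, 2 and 3 and at 7.94 ± 0.906 at 24h. Of 16 B cell markers, 15 fell (camera adjusted p = 3.57e-07, and adjusted p = 0.138 with an estimated correlation), and Cd74 went from 2494 ± 514 to 269 ± 12 TPM. All 10 NK cell markers tested fell (camera adjusted p = 2.62e-04, and adjusted p = 0.276 with an estimated correlation), with a median of −3.17 and the largest fall, −6.85, for Cd7. All 11 erythroid and platelet markers fell (camera adjusted p = 3.95e-06, and adjusted p = 0.179 with an estimated correlation), with the globin Hba-a1 at 425 ± 67.7 TPM in Naive. Of 7 CD4 and regulatory T cell markers, 1 rose and 4 fell (camera adjusted p = 0.289, and adjusted p = 0.445 with an estimated correlation), and Cd4 was at 6.81 ± 2.49 TPM in Naive. Of 12 stromal and endothelial markers listed, only 1 passed the filter for testing, Pecam1, which fell by 2.92. This list therefore does not show RNA of such cells in the Naive libraries. Of 15 T cell markers, 6 fell (camera adjusted p = 5.66e-05, and adjusted p = 0.207 with an estimated correlation), and Cd8a was at 763 ± 24.0 TPM in Naive and 439.9 ± 40.7 at 24h. The B cell fall lay beside that of Klhl6 and Foxo1, and the fall of all these markers beside the falls in every other list at 24h, among them the naive and quiescence genes, the FOXO target genes, the homing receptors and the interferon-stimulated genes.

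**Figure D2:**
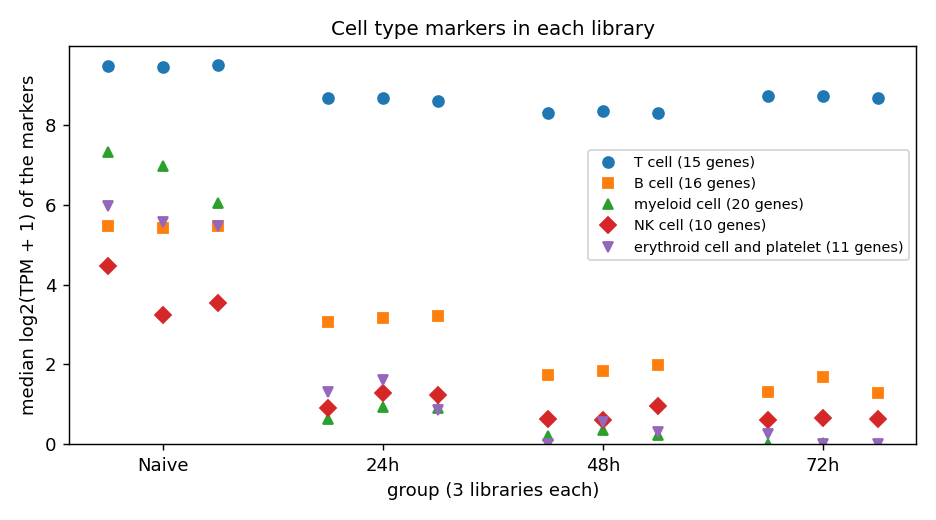
Median log2(TPM + 1) of each set of cell type markers in each library, by group, with 3 libraries per group. T cell markers stayed at 8.31 or above in every library, while the myeloid median went from between 6.06 and 7.32 in Naive to 0.943 or less in every activated library.

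The counts at 24h came from the limma test at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. With a pseudocount of 5, 1641 genes fell. Median-of-ratios scaling shifted the median of all genes from 0.15 to −0.075 and the share of calls that were higher from 55% to 43.6%. Limma voom on recovered reads, chosen after seeing the data, also turned the balance at 24h (3155 higher and 3330 lower) and at 48h (3155 and 3168).

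At 48h vs Naive, 3117 genes rose and 2609 fell. Il2ra reached 969 ± 26.5 TPM, Gzmb 16357 ± 257 and Ifng 5871 ± 186, which are log2 fold changes of 8.75, 8.18 and 8.08. The other genes of largest rise were Tnfrsf9 (7.56), Zbtb32 (7.28), Lif (7.02), Nrn1 (6.92) and Asns (7.02), which encodes asparagine synthetase and stood at 284 ± 2.42 TPM against 1.21 ± 0.183 in Naive. Klf2 remained low at 6.35 ± 0.0682 TPM (−9.24). The other genes of largest fall were markers of other cells, with Hba-a1 and C1qa listed at 0 in all 48h libraries and Hba-a2 (−8.54), Hbb-bs (−8.18), Lyz2 (−8.03), C1qb (−7.53) and S100a9 (−7.53) near 0.

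Single checkpoint receptors rose at 48h while their list split as at 24h. Of 17 inhibitory receptors, 5 rose and 6 fell (camera adjusted p = 0.748, and adjusted p = 0.856 with an estimated correlation). The median of this list was 0.10 and its mean 0.30 where camera placed it on the lower side and fry on the higher (adjusted p = 0.00501), and median-of-ratios scaling turned the median negative. Against Naive, Ctla4 rose by 4.0 to 828 ± 6.46 TPM, Lag3 by 4.33 to 368 ± 32.0, Tigit by 1.98 to 162 ± 5.57, and Pdcd1 by 4.34 to 48.6 ± 3.87, while Havcr2, which encodes TIM-3, was at 7.84 ± 1.51 TPM (0.10, adjusted p = 0.665, and −0.11 with median-of-ratios scaling). Of 20 exhaustion-associated regulators, 5 rose and 6 fell (camera adjusted p = 0.705, and adjusted p = 0.818 with an estimated correlation, on the lower side, where fry gave the higher side at 0.00128), with Tox at 5.45 ± 0.809 TPM (−1.79) and Tcf7 at 150.2 ± 8.82 (−2.99). Of the naive and quiescence genes, 17 of 25 fell (camera adjusted p = 1.19e-08, and adjusted p = 0.203 with an estimated correlation), and of the FOXO target genes 21 of 25 (camera adjusted p = 1.59e-08, and adjusted p = 0.203 with an estimated correlation), with Il7r at 69.5 ± 5.93 TPM (−1.61).

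Metabolic and stress genes at 48h were set against Naive as well. Of 21 glycolysis genes, 19 rose (camera adjusted p = 1.46e-06, and adjusted p = 0.366 with an estimated correlation), with Slc2a1 at 250.0 ± 10.7 TPM (2.13) and the lactate transporter Slc16a3 higher by 5.28. Of 18 integrated stress response genes, 12 rose and 3 fell (camera adjusted p = 0.0393, and adjusted p = 0.481 with an estimated correlation, and 0.0684 with a pseudocount of 0.1), Cth by 6.45 and Trib3 by 4.28. Of 25 IL-2 and STAT5 responsive genes, 17 rose and 2 fell (camera adjusted p = 2.09e-04, and adjusted p = 0.172 with an estimated correlation), and of 34 effector and cytotoxic genes, 16 rose and 9 fell (camera adjusted p = 0.231, and adjusted p = 0.776 with an estimated correlation). Of 40 cell cycle genes, 39 rose (camera adjusted p = 1.11e-11, and adjusted p = 0.211 with an estimated correlation), with Mki67 at 233 ± 24.8 TPM (3.02), and Myc was at 492 ± 13.9 TPM (2.34). With a pseudocount of 5, 1636 genes fell at 48h vs Naive. Median-of-ratios scaling turned the balance of the calls, to 2569 higher and 3107 lower, with the share higher going from 54.4% to 45.3% and the median of all genes from 0.15 to −0.05. The markers of myeloid, NK, erythroid and B cells all fell, in 20 of 20, 10 of 10, 11 of 11 and 16 of 16 genes.

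**Figure D3:**
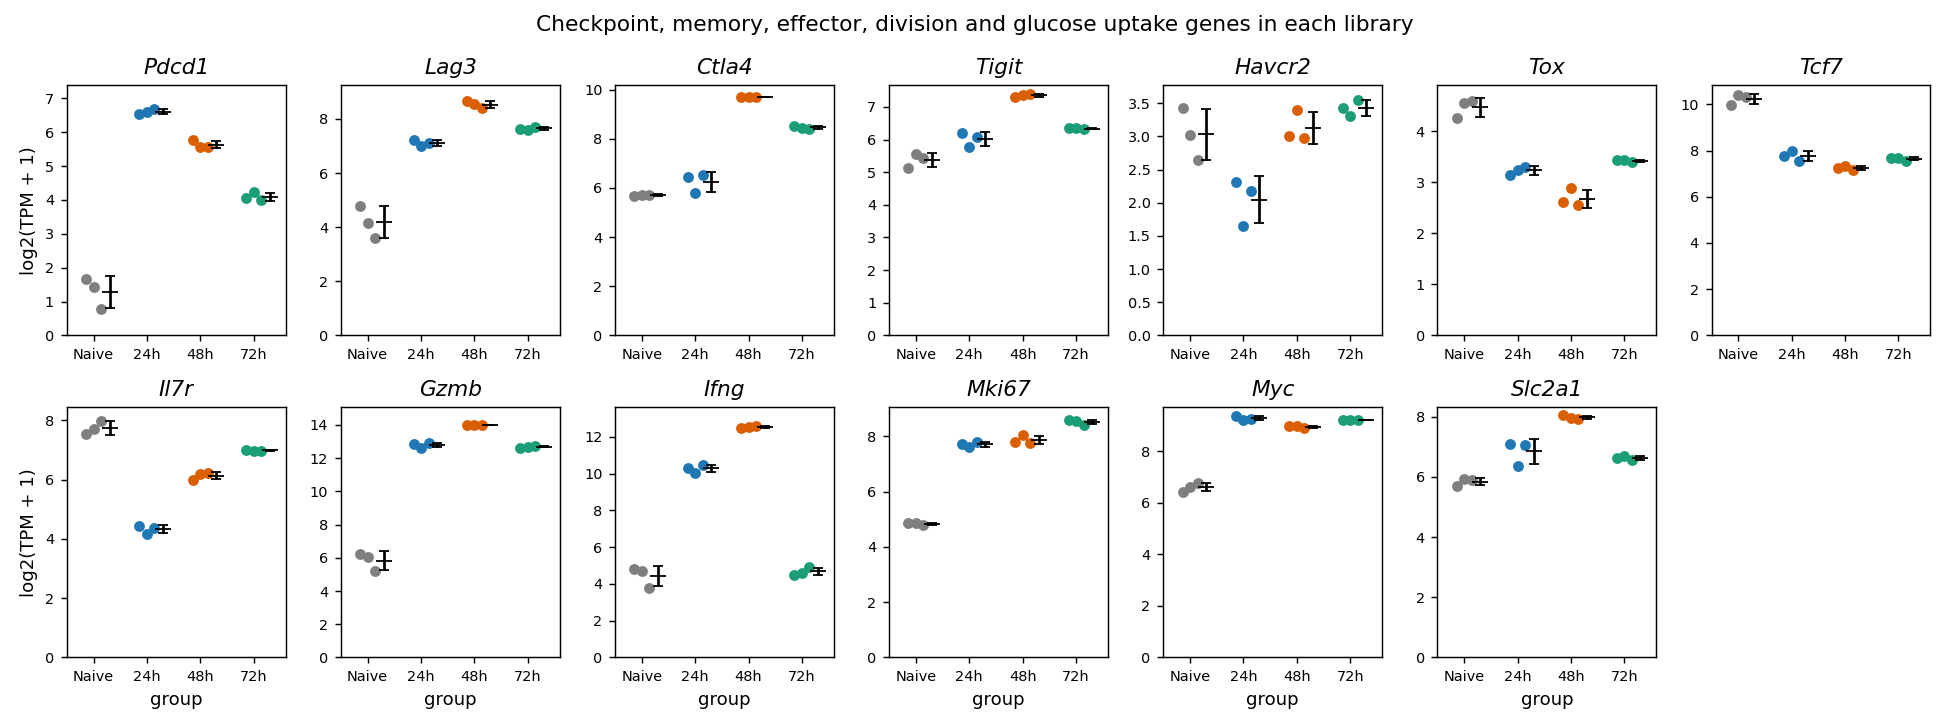
Log2(TPM + 1) of 13 genes in each of the 12 libraries by group. Points are libraries and the bar beside them gives the mean and SD of the 3. Ifng stood at 5871 TPM at 48h and 24.7 at 72h, and Pdcd1 at 96.5 TPM at 24h and 16.1 at 72h.

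At 72h vs Naive, after a day off the plates, 3100 genes rose and 2403 fell. Il2ra stayed high at 1095 ± 43.8 TPM (8.93) and Gzmb at 6558 ± 158 (6.86), while Ifng, at 24.7 ± 3.79 TPM against 21.7 ± 7.74 in Naive, did not pass the test (0.24, adjusted p = 0.305, and −0.04 with median-of-ratios scaling). Tnfrsf8, which encodes CD30, rose by 7.64, Lif by 6.67, Asns by 6.30, Zbtb32 by 6.28, the interferon-inducible GTPase gene Iigp1 by 6.20 and Bnip3 by 6.08. Klf2 was at 23.9 ± 1.43 TPM (−7.48). Hba-a1, Hbb-bs, Lyz2, C1qa, C1qb and S100a9 were listed at 0 in all 72h libraries, and Hba-a2 at 0.0871 TPM.

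Lag3, Ctla4 and Pdcd1 were called above Naive at 72h. Lag3 stood at 199.7 ± 8.31 TPM (3.46 vs Naive), Ctla4 at 352 ± 13 (2.77) and Pdcd1 at 16.1 ± 1.48 (2.80), while Tigit at 79.7 ± 1.44 (0.96) and Havcr2 at 9.78 ± 0.9 (0.40) were not called. Tigit passed the fold minimum without Naive replicate 2 (1.06). Of 17 inhibitory receptors, 4 rose and 7 fell (camera adjusted p = 0.325, and adjusted p = 0.584 with an estimated correlation). Of 20 exhaustion-associated regulators, 4 rose and 9 fell (camera adjusted p = 0.215, and adjusted p = 0.484 with an estimated correlation), with Nr4a1 at −4.49 and Tox at 9.75 ± 0.163 TPM (−1.05), a call lost without Naive replicate 3 (−0.98). Of 25 naive and quiescence genes, 16 fell and 1 rose (camera adjusted p = 3.36e-08, and adjusted p = 0.203 with an estimated correlation), and of 25 FOXO target genes 20 fell (camera adjusted p = 6.04e-09, and adjusted p = 0.203 with an estimated correlation). Tcf7 was at 201 ± 10.8 TPM (−2.58), and Il7r (−0.76) lay under the fold minimum, though it was called lower with median-of-ratios scaling (−1.04) and quantile normalization (−1.08). Of 30 interferon-stimulated genes, 8 rose and 8 fell (camera adjusted p = 0.824, and adjusted p = 0.925 with an estimated correlation), with a median of 0.22 where camera placed the list on the lower side and fry on the higher (adjusted p = 0.0126), and median-of-ratios scaling turned the median negative.

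Division and lipid genes were counted at 72h vs Naive. Of 40 cell cycle genes, 39 rose (camera adjusted p = 5.93e-12, and adjusted p = 0.211 with an estimated correlation), with Mki67 at 367 ± 21.8 TPM (3.68), and Myc was at 587 ± 2.63 (2.59). Of 24 cholesterol synthesis genes, 22 rose (camera adjusted p = 1.34e-07, and adjusted p = 0.239 with an estimated correlation), Idi1 by 3.91 and Fdps by 3.83. Of 21 glycolysis genes, 18 rose (camera adjusted p = 9.25e-06, and adjusted p = 0.409 with an estimated correlation), although Slc2a1 at 98.0 ± 3.86 TPM lay under the fold minimum (0.79). With a pseudocount of 5, 1483 genes fell at 72h vs Naive, and median-of-ratios scaling moved the share of calls that were higher from 56.3% to 43.4% and the median of all genes from 0.21 to −0.04. All 20 myeloid, 10 NK cell, 11 erythroid and platelet and 16 B cell markers tested fell beside these groups.

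Of all genes tested, 2178 rose and 1869 fell in each of the 3 comparisons with Naive. Independent lists of these sizes would share 196.6 and 104.4 genes, a reference that leaves out the sharing of the Naive libraries. Groups simulated without change shared none in 20 simulations. That outcome was fixed in advance, since unchanged groups give almost no calls. How far the shared libraries raise the overlap of genes that do change was not measured. The 3 comparisons share the Naive libraries, which were too few to be split between them. In all, 39 genes were called higher than Naive at 1 time and lower at another.

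Between 24h and 48h, with the cells still on the plates, 625 genes rose and 388 fell. Without the fold minimum the balance turned, to 2786 higher and 3789 lower. Il24, a cytokine of the IL-10 family, went from 2.34 ± 0.208 to 108 ± 4.65 TPM (5.03), Il13 from 1.28 ± 0.991 to 42.5 ± 3.40 (4.36), Il23a from 0.908 ± 0.148 to 44.8 ± 1.12 (4.59) and the metallothionein Mt2 from 12.7 ± 3.52 to 239.7 ± 18.1 (4.16). Tgm2 (4.76), Emilin2 (4.42), Mgarp (3.75) and H2-Q10 (3.74) rose as well. The chemokine gene Ccl1 fell by 3.58 and Xcl1 from 1979.9 ± 62.0 to 345 ± 23.8 TPM (−2.52), together with Fam26f (−2.99), Hist1h3a (−2.80), Chst2 (−2.68), Hist1h2bh (−2.52), Gbp2 (−2.49) and Egr4 (−2.36). Mgarp was listed at 0 in 24h replicate 2, the library that also held the lowest Bnip3 of its group, at 16.5 TPM against 73.5 and 91.7.

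Ifng rose by 2.24 and Gzmb by 1.20 from 24h to 48h, the latter call lost with quantile normalization (0.59, adjusted p = 0.0696). Of 34 effector and cytotoxic genes, 13 rose and 5 fell (camera adjusted p = 0.00168, and adjusted p = 0.484 with an estimated correlation), and of 25 IL-2 and STAT5 responsive genes 12 rose (camera adjusted p = 1.46e-05, and adjusted p = 0.154 with an estimated correlation), Il10 by 2.87 and Tnfrsf8 by 2.48. Of 17 inhibitory receptors, 4 rose and 1 fell (camera adjusted p = 0.376, and adjusted p = 0.614 with an estimated correlation). Ctla4 rose by 3.45, Lag3 by 1.42, Tigit by 1.34 and Havcr2 by 1.09, while Pdcd1 differed by −0.98, under the fold minimum, and was called without 24h replicate 1 (−1.02) or 48h replicate 1 (−1.04). The Havcr2 call was lost without 24h replicate 2 (0.89) or 48h replicate 2 (0.95). Il7r rose by 1.81, whereas Tcf7 (−0.53), Tox (−0.55), Myc (−0.33) and Mki67 (0.16) lay under the fold minimum.

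Of 18 integrated stress response genes, 10 rose and 0 fell from 24h to 48h (camera adjusted p = 6.42e-11, and adjusted p = 0.154 with an estimated correlation), with Vldlr higher by 3.45, Cth by 3.07 and Asns by 2.73. Of 21 glycolysis genes, 10 rose (camera adjusted p = 1.57e-08, and adjusted p = 0.283 with an estimated correlation), Slc2a3 by 3.13 and Aldoc by 3.01, and Slc2a1 rose by 1.13, a call lost without 24h replicate 2 (0.89). In that library 20 of the 21 glycolysis genes lay below both other 24h libraries, by a median of −0.49 over the list, and without it 5 of the list were called higher (chosen after seeing the data). Of 24 apoptosis and p53 response genes, 8 rose and 1 fell (camera adjusted p = 0.0648, and adjusted p = 0.211 with an estimated correlation, and 0.049 with quantile normalization), Cdkn1a, which encodes a cell cycle inhibitor, by 3.66. Of 16 replication-dependent histone genes, 12 fell (camera adjusted p = 0.00236, and adjusted p = 0.172 with an estimated correlation). Of 25 FOXO target genes, 9 rose and 2 fell (camera adjusted p = 0.00338, and adjusted p = 0.445 with an estimated correlation), with Ddit4 at 3.44 and Bcl2l11 at −2.17. Without 24h replicate 2, 7 of the list rose and 2 fell, and its median went from 0.40 to 0.30 (chosen after seeing the data). Of 16 B cell markers, 9 fell and 0 rose (camera adjusted p = 2.75e-05, and adjusted p = 0.172 with an estimated correlation). Of 7 CD4 and regulatory T cell markers, 3 rose, Ctla4 among them, and 0 fell, or 2 and 0 without 24h replicate 2 (chosen after seeing the data). Camera gave this list an adjusted p of 0.0409, 0.207 with an estimated correlation and 0.0529 with median-of-ratios scaling. These markers rose beside the checkpoint, effector and IL-2 responsive genes of this step. With a pseudocount of 5 the counts were 298 higher and 150 lower, and limma voom on recovered reads, chosen after seeing the data, gave 952 higher. A pseudocount of 0.1 gave 700 lower.

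From 48h to 72h, the interval in which the cells left the plates, 355 genes rose and 407 fell. Without the fold minimum the balance turned here too, to 2964 higher and 2402 lower. Ifng fell from 5871 ± 186 to 24.7 ± 3.79 TPM (−7.84, SE 0.21, adjusted p = 7.90e-11), the chemokines Ccl3 from 1547 ± 52.7 to 16.5 ± 3.12 (−6.48), Ccl4 from 781 ± 37.9 to 8.45 ± 2.31 (−6.40) and Xcl1 from 345 ± 23.8 to 6.45 ± 2.07 (−5.57). The cytokine genes Il3 and Il23a, at 62.5 ± 8.08 and 44.8 ± 1.12 TPM at 48h, were listed at 0 in all 72h libraries, and Crabp2 (−5.43) and Ramp3 (−3.99) fell too. Cxcr3, a chemokine receptor of effector and memory T cells, rose from 7.04 ± 1.55 to 77.3 ± 2.55 TPM (3.30), Emp1 from 5.32 ± 0.558 to 81.6 ± 4.83 (3.71) and Ctla2a from 37.7 ± 0.433 to 378 ± 23.6 (3.29). Ctla2b (3.65), S100a6 (3.63), Glipr1 (3.20), Tcrg-C2 (2.95) and Fgl2 (2.72) completed the largest rises. Ctla2a and Ctla2b, the globin genes, the histone genes and the Klra genes are near-identical families, and how shared reads were assigned is not given in the sources used here.

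Of 30 TCR-induced early genes, 15 fell and 1 rose from 48h to 72h (camera adjusted p = 4.33e-10, and adjusted p = 0.104 with an estimated correlation). The nuclear receptors Nr4a3 (−2.90), Nr4a1 (−2.57) and Nr4a2 (−2.20), and Il2 (−3.94), fell. Of 34 effector and cytotoxic genes, 8 rose and 9 fell (camera adjusted p = 0.216, and adjusted p = 0.775 with an estimated correlation), with Gzmb at −1.32, and at −0.98 with quantile normalization, under the fold minimum. Of 17 inhibitory receptors, 5 fell and 1 rose (camera adjusted p = 0.0139, and adjusted p = 0.211 with an estimated correlation), namely Cd200 (−2.36), Pdcd1 (−1.54), Lilrb4a (−1.49), Ctla4 (−1.23) and Tigit (−1.01, or −0.99 without 48h replicate 3) among the lower. Lag3 (−0.88) and Havcr2 (0.30) were not called. Of 20 exhaustion-associated regulators, 5 fell and 1 rose (camera adjusted p = 0.0495, and adjusted p = 0.303 with an estimated correlation, and 0.0822 with median-of-ratios scaling, 0.0684 with quantile normalization, 0.0539 with a pseudocount of 0.1 and 0.0701 with a replicate block), the latter being Prdm1 (1.92), and Tox (0.74) and Tcf7 (0.41) lay under the fold minimum.

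Of 30 interferon-stimulated genes, 10 rose from 48h to 72h and none fell (camera adjusted p = 8.66e-08, and adjusted p = 0.203 with an estimated correlation), among the higher Rtp4 (2.12) and Cmpk2 (1.76). Few naive and quiescence genes were called, 3 of 25 rising and 1 falling (camera adjusted p = 0.899, and adjusted p = 0.965 with an estimated correlation). Klf2 rose by 1.76 and S1pr1 by 1.29, Ccr7, a lymph node homing receptor, fell by 1.51, and Il7r (0.86) lay under the fold minimum. Of 18 integrated stress response genes, 6 fell and 0 rose (camera adjusted p = 1.86e-08, and adjusted p = 0.172 with an estimated correlation), with Cth at −3.40. Of 21 glycolysis genes, 3 fell (camera adjusted p = 5.70e-05, and adjusted p = 0.447 with an estimated correlation), Slc2a1 by 1.34. The call of Slc16a3 (−1.08) was lost without any single library of the 6, with adjusted p between 0.0711 and 0.11. None of 40 cell cycle genes was called (camera adjusted p = 0.0011, and adjusted p = 0.515 with an estimated correlation), Mki67 differing by 0.66 and Myc by 0.25. Of 16 B cell markers, 2 fell and 1 rose (camera adjusted p = 0.00165, and adjusted p = 0.203 with an estimated correlation), the latter being Ighm (1.11), which went from 217 ± 2.09 to 471 ± 17.8 TPM.

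Of the 3117 genes higher at 48h than in Naive, 239 were lower at 72h than at 48h (7.7%), and of the 2609 lower at 48h, 174 were higher at 72h (6.7%). For the genes that turned back, lists drawn independently would share 100.4 and 73.3, without regard to the shared 48h libraries. Simulated unchanged groups gave 0 such genes in each of 20 simulations, an outcome fixed in advance because almost no gene is called there. Neither reference shows how far the shared 48h libraries raise these counts. With a pseudocount of 5 these turned-back genes numbered 170 in all, and with a pseudocount of 0.1 they numbered 652. For the step from 48h to 72h, a pseudocount of 5 gave 147 genes higher and 171 lower, and a pseudocount of 0.1 gave 584 and 663.

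**Figure D4:**
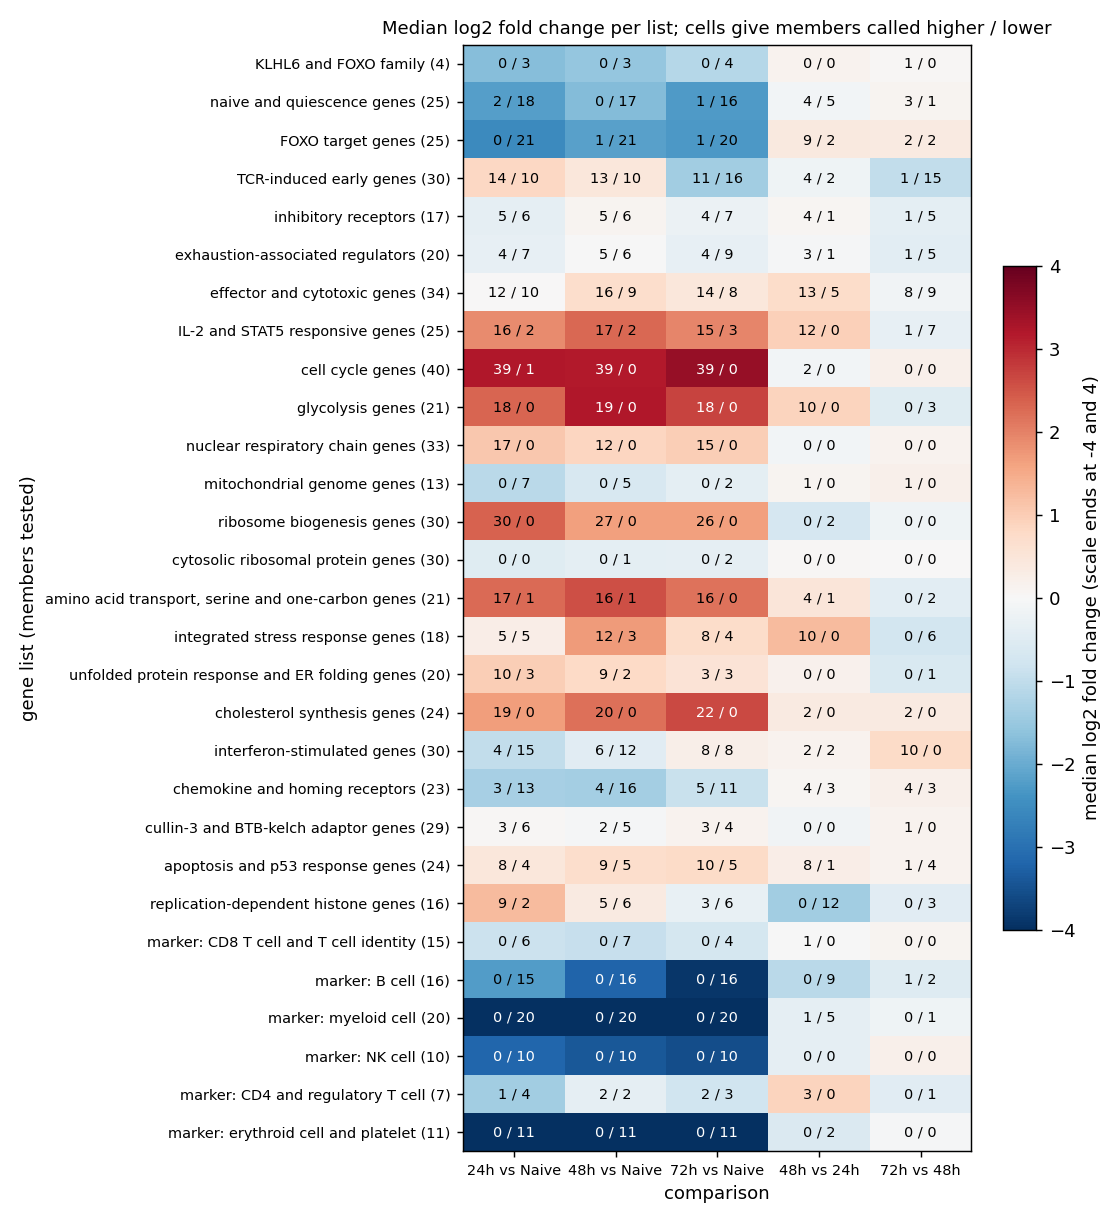
Median log2 fold change of each gene list (rows, with members tested) in each comparison (columns), with the members called higher and lower written in each cell. Cell cycle genes were higher in 39 of 40 members at 24h vs Naive, and myeloid markers lower in 20 of 20.

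The list tests carry a limit of their own. Camera with its preset correlation called 79 of 140 tests of a list in a comparison, none of these calls held with an estimated correlation (33 of the 140 had an unadjusted p under 0.05 there), and fry called 120. Of 100 groupings of the 12 libraries, the real one included, 13 gave at least 79 calls. The 3 Naive libraries cannot be spread evenly over 4 groups, so a regrouping keeps part of the difference between Naive and activated cells. The count therefore does not decide whether the list calls exceed chance. The counts of members called were the same when adjusted over the list alone in all 150 combinations of list and comparison.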

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

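Every test of an explanation below was chosen after the result was seen. The log2 fold change against Naive differed between times for Klhl6 and several of the genes fixed in advance, with the difference itself past the threshold in limma. Naive cancels in such a difference, so these are the values of 48h vs 24h and of 72h vs 48h given above. From 24h to 48h the log2 fold change against Naive changed by 1.09 for Havcr2, 1.42 for Lag3, 1.34 for Tigit and 3.45 for Ctla4. It changed by 1.81 for Il7r, 1.20 for Gzmb, 2.24 for Ifng and 1.13 for Slc2a1. From 48h to 72h it changed by 1.07 for Klhl6, −1.54 for Pdcd1, −1.01 for Tigit, −1.23 for Ctla4, −1.32 for Gzmb, −7.84 for Ifng and −1.34 for Slc2a1.

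A further 15 named genes were called higher than Naive at 1 time and lower at another, each with the difference between those times past the adjusted threshold. Genes of TCR signalling and chemokines stood above Naive at 24h and below it at 72h, at 1.5 and −1.74 for Nr4a3, 2.03 and −1.27 for Egr4, 1.80 and −2.08 for Egr3, 5.72 and −1.39 for Ccl3 and 4.09 and −3.34 for Ccl4. Below Naive at 24h and above it at 72h were Prdm1 at −1.03 and 2.31, Ddit4 at −1.70 and 1.42, Cmpk2 at −1.30 and 1.43, Tcrg-C2 at −1.74 and 1.60, Ctla2a at −2.85 and 1.67, Ctla2b at −3.20 and 1.62 and Emilin2 at −2.80 and 1.08. At 24h, 48h and 72h Tgm2 was at −3.01, 1.75 and −1.04, Cxcr3 at 0.59, −1.05 and 2.25 and H2-Q10 at −2.48, 1.26 and 0.70, and at 48h Ddit4 and Emilin2 were above Naive as well, at 1.74 and 1.62. The falls at 24h lay beside those of the myeloid, NK and B cell markers, and RNA of such cells in Naive was not tested for these genes.

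Klhl6 fell from Naive and rose again from 48h to 72h. Scaling of the TPM values was argued against as the whole cause of either, since it moves all genes alike, while Klhl6 less the median of all genes was −1.45 or lower at each time vs Naive and 1.05 from 48h to 72h (SE 0.105). TPM gives a gene's share of its library. Here and for the sets of genes below, changes in the amount of a transcript per cell were therefore not measured. RNA from B cells was argued against for the rise, since the B cell markers had a median of −0.52 (SD 0.605) from 48h to 72h, with Cd74 at −1.59, although Ighm rose by 1.11. For the fall at 24h, B cell RNA in the Naive libraries and a fall within the T cells cannot be told apart, since the B cell markers fell too, with a median of −2.24. Activation and time in culture stay open as untested biological explanations, and for the rise the removal from the plates as well.

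The 10 early-response genes Cd69, Nr4a1, Nfkbid, Nfkbia, Cd83, Tnfaip3, Fos, Fosb, Junb and Dusp2 were called lower than Naive at all 3 times. RNA from myeloid cells was argued against for these genes as a set. They differed by a median of 0.12 (SD 0.298) between Naive replicates 1 and 3, while the myeloid markers differed by 1.36 (SD 0.441). Fos was an exception, at 400, 368 and 225 TPM in Naive replicates 1, 2 and 3, so for Fos myeloid RNA was not argued against. Each of the 10 lay at −1.24 or lower against the median of all genes at each time. They were chosen because they were called lower, so this outcome was fixed in advance and does not test scaling. RNA from B cells cannot be told apart from expression by the T cells, since the B cell markers differed by only 0.17 between the same libraries (SD 0.374). Handling during isolation, which no group of the design separates from the Naive state, was not tested.

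Of the effector and cytotoxic genes, 9 were lower at 72h than at 48h, namely Gzmb, Gzmc, Prf1, Ifng, Ccl3, Ccl4, Xcl1, Serpinb9 and Serpinb6b. Each of the 9 lay at −1.34 or lower against the median of all genes. They were chosen because they were called lower, so this outcome was fixed in advance and does not test scaling. With quantile normalization Gzmb lay at −0.98, under the fold minimum. Loss of NK cells was argued against for the 9 as a set. The highest NK cell marker, Cd7, stood at 1.90 TPM (SD 0.41) at 48h while the 9 genes lost a median of 663 TPM. Gzmc was an exception with the smallest loss, 16.8 TPM, so for Gzmc the loss of NK cells was not argued against. Removal from the plates and a longer time in culture, which the design joins in the 72h group, stay open as untested biological explanations.

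Other splits of the same libraries were counted for each number of called genes. The 3 comparisons with Naive gave 5902, 5726 and 5503 genes, against at most 0, 1 and 0 in any other split, and the steps to 48h and to 72h gave 1013 and 762, against at most 0 and 1. With 10 splits of 6 libraries the share cannot go under 0.05. For the F test over the 4 groups, chance was excluded, as 1 of 100 groupings, the real one, gave 11889 genes and the highest other gave 7938. For the list tests, 13 of 100 groupings gave at least the 79 calls of the real one, and the highest gave 86. Regroupings keep part of the difference between Naive and activated cells, as the 7938 genes show, so this neither excludes chance nor argues for it.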

How the results depend on the processing

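Of 9228 values of named genes under an alternative, 9055 kept their direction and side of the threshold and 7 turned, as did 687 and 16 of 840 list tests. Havcr2 at 48h vs Naive turned with median-of-ratios scaling (−0.108), voom (−0.0322) and without Naive replicate 3 or 48h replicate 2, where 1 library left out gave −0.0928 to 0.295. Ifng at 72h vs Naive turned with median-of-ratios scaling (−0.0365), quantile normalization (−0.0173) and without Naive replicate 3, where 1 library left out gave −0.0839 to 0.43. None of these values or their originals was called. No list that turned passed camera with its preset. Fry turned inhibitory receptors at 24h and 48h vs Naive (adjusted p = 0.346 and 0.00501), effector genes at 24h (0.000328), exhaustion-associated regulators at 48h (0.00128), CD4 markers at 48h and 72h (2.44e-05 and 0.0124), interferon-stimulated genes at 72h and from 24h to 48h (0.0126 and 0.0997) and cullin-3 adaptors at 72h (0.449). It compares a list with no other genes, by construction. Median-of-ratios scaling turned effector genes at 24h (0.769) and ribosomal protein genes from 48h to 72h (0.732). Quantile normalization turned the unfolded protein list at 72h vs Naive (0.936) and, from 24h to 48h, TCR-induced genes (0.75, and 0.939 with a pseudocount of 0.1), respiratory chain genes (0.945) and mitochondrial genome genes (0.944), and the cause was not tested. Without a fold minimum, counts higher and lower were 5796 and 4623 (24h vs Naive), 5830 and 4636 (48h), 6000 and 4398 (72h), 2786 and 3789 (48h vs 24h) and 2964 and 2402 (72h vs 48h), by construction, and in the last 2 the balance turned. A pseudocount of 5, which shrinks changes of genes with low values, gave 1641, 1636 and 1483 lower against Naive, 298 and 150 from 24h to 48h, 147 and 171 from 48h to 72h, and 170 genes that turned back. A pseudocount of 0.1 gave 700 lower from 24h to 48h, 584 and 663 from 48h to 72h, and 652 that turned back. Limma treat, a stricter test by construction, gave 210 and 64, then 103 and 109. Limma voom on recovered reads, chosen after seeing the data, gave 952 higher from 24h to 48h and 544 and 665 from 48h to 72h, and the cause was not tested.

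The Klhl6 difference from 24h to 48h missed the threshold with no filter (−0.28), median-of-ratios scaling (−0.24), quantile normalization (−0.21), no trend (−0.28), a fit on the 2 groups (−0.28) and voom (−0.26). With 1 library left out it ran from −0.35 to −0.15, and it missed the threshold without 24h replicate 2 or any 48h replicate. The Foxo1 difference from 24h to 48h passed it with median-of-ratios scaling (0.21), quantile normalization (0.24), a fit on the 2 groups (0.17), library weights (0.19), voom (0.20) and, chosen after seeing the data, without the 3 Naive libraries (0.17). From 48h to 72h Foxo1 passed it with a fit on the 2 groups (0.18), library weights (0.19) and without the 3 Naive libraries (0.18). The fits on the 2 groups and without the Naive libraries left the Foxo1 change as in the main fit, which pools the spread over all 4 groups. There only the spread and the adjustment of the p-value differed. For the other settings the cause was not tested, nor was it for Klhl6. Of 140 list tests, camera called 79, and 0 with an estimated correlation (33 at an unadjusted p under 0.05), and fry called 120. Replicate numbers did not pair the libraries, with r between −0.0522 and 0.0894 over 18 pairs of the same number.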

Other observations

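Every test below was chosen after the values were seen. A list of 26 genes known to respond to low oxygen was written after Bnip3 and Mgarp were seen to rise, and 7 of its genes also stand in lists fixed earlier. From 24h to 48h, 19 of the 26 genes rose and none fell, with a median of 1.90, and from 48h to 72h 8 fell and none rose. Bnip3 and Mgarp are among the 26, so a test of the first step is not independent of the choice of list. Camera gave an adjusted p of 6.86e-14 for that step. With an estimated correlation its p was 0.0459, and adjusted p = 0.23 over the 5 comparisons, so whether the genes rose as a set stays open. Low oxygen in dense culture may be one explanation, but neither oxygen nor cell density is given, and it was not tested. In 24h replicate 2, 25 of the 26 genes lay below both other 24h libraries, by a median of −0.52 against 0.0031 for all genes, with Bnip3 at 16.5 TPM against 73.5 and 91.7.

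Transcripts of mitochondrial genome genes took between 9.53% and 11.29% of TPM in the Naive libraries and between 4.57% and 6.8% in the others. Ribosomal protein genes took between 19.02% and 19.6% in Naive and between 13.82% and 16.17% in the others.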
